A study of Danio rerio with 43 samples.

How the data were processed

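RNA was extracted from 43 zebrafish intestines with RNeasy mini kits and sequenced after standard Illumina library preparation, per the labels' protocols. The design text describes 6 study groups of 18 adult AB fish each. Of these, 43 fish in the 6 groups were sequenced, in groups of 6 to 9. Each library was assigned to its diet and infection state by its title. Sex, tank, sampling day and worm burden of single fish are not given in the sources used here, and neither are the aligner, the counting tool, the annotation, the strandedness or the trimming of adjoining organs. The submitters' processing notes name the genome build GRCz11 and DESeq2, without versions.

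The deposited table holds raw read counts per gene, whole numbers that the authors had not normalised, with 33218 gene rows: 25431 Ensembl genes, of which 25016 have a symbol, and 7787 gene models of the submitters' own, of which 2577 have one. Symbols came from the table itself or from a reference table of gene names. A further 18 lines held only overflowing annotation text and were left out. The submitters' own gene models took 1.52% to 9.98% of the reads of a library. Coordinates are not used here, and every column was matched to a library by its name. Library totals ran from 28.68 M to 40.24 M reads (median 33.8 M), so that depth differed little between libraries and the spread between fish set the precision. Reads without molecular identifiers are not independent molecules, and shares of reads cover counting error only.

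Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group (22690 genes kept), a model with a mean per group over all 43 libraries, and the quasi-likelihood F test. All groups were fitted together so that they share an estimate of spread. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. There were 13 comparisons: infection on each of the 3 diets and averaged over them, each added diet against control in uninfected fish, in infected fish and averaged, egg against inulin, and the interaction of infection with each diet. Log2 fold changes are given with an approximate standard error, the absolute log2 fold change divided by the square root of the F statistic. Adjusted p-values printed beside a gene are from the quasi-likelihood F test unless another tool is named. CPM values use the TMM library sizes.

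Before the data were examined, 55 gene lists of pathways, cell types and neighbouring organs were fixed from general knowledge, together with the comparisons, the model, most alternatives and the rule for named genes. Of the lists, 54 had at least 5 tested members and were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Over all comparisons camera called 249 list changes with the preset correlation, 0 held with the estimated correlation, and fry called 28. A list adjusted over the list alone was corrected over its own tested members. Genes were named by rule: per comparison the 8 largest rises and 8 largest falls among changed genes with a symbol that is no clone or predicted name and a mean of at least 1 CPM in a compared group (5 per direction for an interaction), and up to 4 changed members of each described list by smallest p, or 2 members where none passed. The text leaves out 1 gene value that this rule picks, which is not reported here. Genes named outside this rule are said to be chosen after their values were seen.

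Alternatives planned in advance were DESeq2's size factors in place of TMM, no filter on low counts, the Wald test of DESeq2 1.42.0, a fit of only the groups compared, library numbers up to 36 against 38 to 72 as a covariate (20 and 23 libraries), the replicate number as a block, 2 surrogate variables from sva 3.50.0, and the mean log expression of the exocrine pancreas, liver and ovary lists as covariates. After seeing the data, fits without the 4 gonad-rich libraries (39 libraries left) and with the 2 closest libraries summed were added. For infection averaged over the diets, a fit without the 9 libraries in which the ovary and testis lists together took over 0.05% of the reads was added as well (34 libraries left). Those 2 libraries, inulin infected 5 and 6, had a median chi-square per gene of 2.99 against 5.71 for the next closest pair and 26.3 for the median of 903 pairs. Sampling noise alone gives 0.455. In this pair 23 genes were present in 1 library and absent in the other, against at least 92 in any other pair (median 367). The counts do not show whether the 2 libraries come from separate fish. They were kept as the labels list them.

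The procedure was tested on simulated counts with 200 genes changed by known folds, drawn from the means, library sizes and spread of the real libraries. For infection averaged over the diets it recovered 57% of the genes changed 2-fold and 85% of those changed 4-fold, with 33 false calls among 22233 genes. These made up 18.9% of the 175 calls, so that the adjusted p threshold of 0.05 was not held there. For infection on the egg diet the shares were 6% and 62% (0 false calls among 22238 genes), for egg against control averaged over infection 37% and 80% (8 false calls among 22236 genes, 6.4% of the calls), and in infected fish 15% and 71% (4 false calls among 22238 genes). A list raised 2-fold was recovered by camera with the preset correlation in both simulations that held such a list. In them 0 of the 53 other lists were called. Each gene was drawn independently, so the members of a list were not correlated. Genes of a shared tissue did not move together across libraries either. The simulations therefore say nothing about false calls where genes move together, in lists or among all genes. Other splits of the real libraries, described at the end, called up to 1061 genes for infection on the egg diet (median 0). For egg against control averaged over infection they called up to 2347 (median 0).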

Results

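Gene expression was measured by RNA sequencing in 43 intestines of adult zebrafish of the AB wildtype line. The fish had been fed a control diet, the control diet with 20% inulin (a fermentable plant fibre) or a high-fat diet based on egg yolk powder, here called the egg diet. After 14 days on the diet, a part of the fish was exposed to eggs of Pseudocapillaria tomentosa, a nematode that lives in the fish gut, and intestines were collected 29 or 30 days after the first exposure. The 6 groups held 6 uninfected and 9 infected fish on the control diet, 6 and 8 on inulin, and 6 and 8 on the egg diet, so that 18 uninfected and 25 infected fish entered the comparisons. Each library is taken as a separate fish, and p-values measure the spread between fish. The libraries inulin infected 5 and 6 were closer to each other than any other pair, and the counts do not show that they come from separate fish, so n may be lower by 1 in that group. The libraries held 28.68 M to 40.24 M counted reads (median 33.8 M), and 22690 genes were tested. The comparisons asked how infection changed the intestinal transcriptome on each diet, how the diets differed, and whether diet altered the response to the worm.

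The libraries differed widely in the share of reads on genes of neighbouring organs. Genes of the exocrine pancreas, whose lobes lie along the fish gut, took between 0.0608% and 35.4% of the reads in uninfected fish (median 14.5%, n = 18) and between 0.072% and 24.9% in infected fish (median 2.54%, n = 25). In 4 uninfected libraries, and in 0 of the 25 infected ones, more than 1% of the reads fell on ovary or testis genes. These gonad-rich libraries were control uninfected 5 with 1.31% on testis genes, control uninfected 6 with 1.78% on ovary genes, inulin uninfected 3 with 8.37% and egg uninfected 5 with 10% on ovary genes. The next highest ovary shares were in infected libraries, 0.254% in egg infected 8, 0.211% in control infected 9 and 0.0986% in inulin infected 1. The labels give neither sex nor which organs were trimmed away. The number of changed genes in each comparison is therefore given over all libraries and again without these 4, an alternative chosen after seeing the data.

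**Figure D1:**
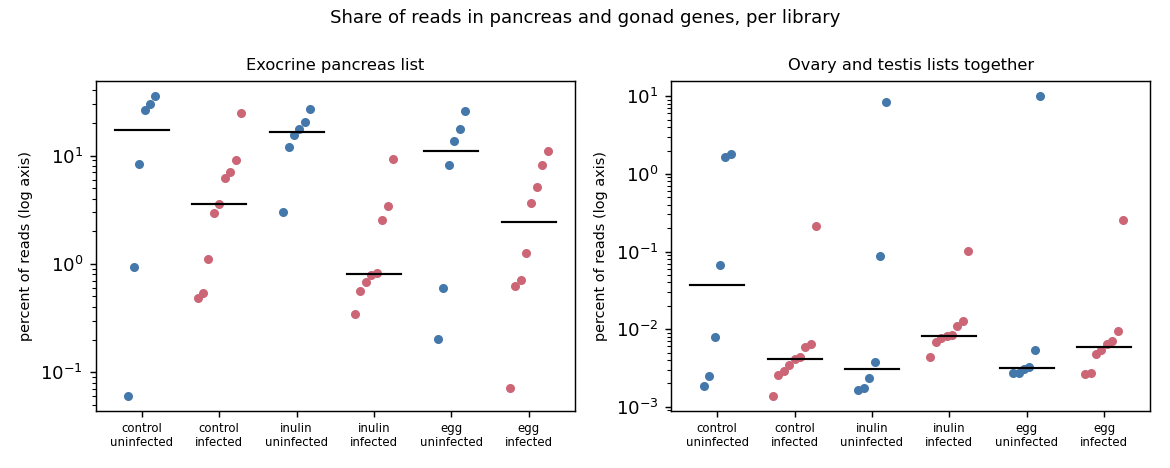
Percent of reads (log axes) in the exocrine pancreas list (left) and in the ovary and testis lists together (right) for each library, by group; points are libraries and black lines are medians. The exocrine share has a median of 14.5% in the 18 uninfected and 2.54% in the 25 infected libraries, and the 4 gonad-rich libraries are all uninfected.

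Infection raised type 2 cytokine genes and genes of tuft cells, the chemosensory epithelial cells that respond to intestinal worms in mammals. The gene il13 (ENSDARG00000077809) encodes the type 2 cytokine best known for driving the expulsion of worms. Averaged over the 3 diets, it rose from a mean of 1.81 to 71 CPM (read counts scaled to library size). The log2 fold change was 5.33 ± 0.68 (approximate SE from the F statistic, adjusted p = 3.3e-06, n = 25 against 18). All 25 infected libraries lay above the median of the uninfected ones and 16 lay above every uninfected library. Its partner cytokine il4 (ENSDARG00000087909) rose by 5.53 ± 1.03 (adjusted p = 3e-04), and the receptor gene il4r.1 rose by 0.82 ± 0.22 (adjusted p = 0.00546). Of the 15 tested genes of the type 2 list 8 rose and 0 fell, and the same numbers held adjusted over the list alone (adjusted p = 0.215 with an estimated correlation). A fit added after seeing the data left out the libraries richest in ovary and testis genes (12 uninfected and 22 infected left). There 4 of the 15 type 2 genes rose and 0 fell. Of the 15 tested tuft cell genes 5 rose and 0 fell in that fit. Over all libraries 7 tuft cell genes rose and 0 fell, again with the same numbers adjusted over the list alone (adjusted p = 0.0624 with an estimated correlation). They included pou2f3 (ENSDARG00000052387), the transcription factor that specifies tuft cells, at 2.91 ± 0.45 (adjusted p = 4.24e-05), gfi1b at 3.52 ± 0.85 (adjusted p = 0.00211) and ltc4s, which makes leukotriene C4, at 2.39 ± 0.47 (adjusted p = 0.000366). Among smooth muscle genes 4 of 24 rose and 0 fell (3 and 0 adjusted over the list alone). They were led by the myosin heavy chain gene myh11b (ENSDARG00000100972), which rose by 3.78 ± 0.52 (adjusted p = 9.16e-06) from 4.09 to 52.8 CPM.

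**Figure D2:**
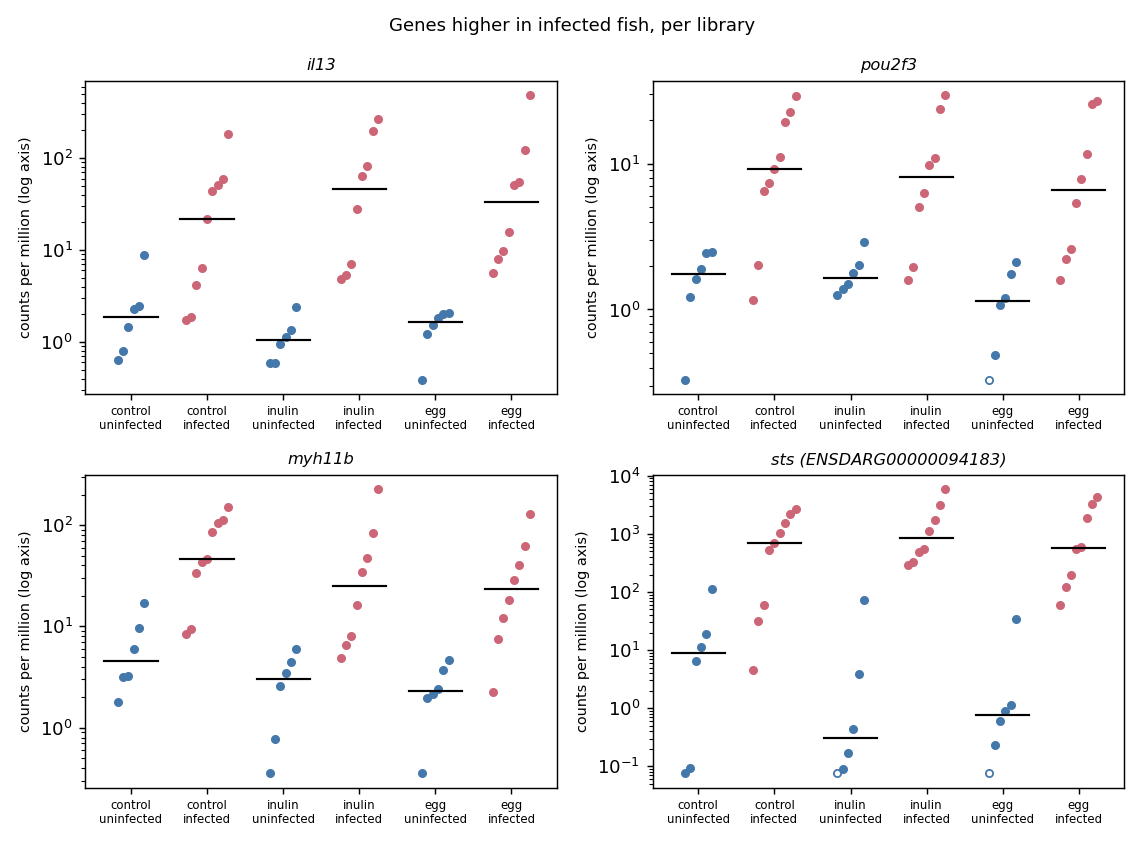
CPM (log axes) of il13, pou2f3, myh11b and sts for each library, by group; points are libraries, black lines are medians, and hollow points had no reads and stand at the lowest value above zero. For sts, 21 of the 25 infected libraries lie above every uninfected library.

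Inflammatory and myeloid genes rose as well. Of the 35 acute inflammation genes 15 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 0.215 with an estimated correlation), among them the neutrophil-attracting chemokine gene cxcl8b.1 (ENSDARG00000102299) at 3.31 ± 0.54 (adjusted p = 8.16e-05) and the prostaglandin synthase ptgs2b at 1.78 ± 0.38 (adjusted p = 0.000722). Of 25 neutrophil genes 12 rose and 1 fell (15 and 1 adjusted over the list alone; adjusted p = 0.215 with an estimated correlation), with the collagenase mmp13a (ENSDARG00000012395) at 4.84 ± 1.03 and the chemokine receptor cxcr2 at 1.56 ± 0.37. Of 30 macrophage and dendritic cell genes 10 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.32 with an estimated correlation), with irf8 at 2.02 ± 0.40 (adjusted p = 0.000397) and the scavenger receptor marco at 1.15 ± 0.30 (adjusted p = 0.0044). Interferon genes gave 10 rises and 1 fall among 32, also adjusted over the list alone (adjusted p = 0.39 with an estimated correlation), with gbp1 at 1.69 ± 0.33 and mxc at 2.27 ± 0.66. In the lymphocyte lists 1 rose and 2 fell among 25 T cell genes (0 and 1 adjusted over the list alone), and 2 rose and 2 fell among 22 B and plasma cell genes (2 and 1 adjusted over the list alone). The B cell list's rises were btk (2.3 ± 0.33, adjusted p = 1.39e-05) and blnk (1.23 ± 0.23), which act in B cell receptor signalling and are also used by myeloid cells.

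The largest single rises were in genes outside these groups. The sulfatase gene sts (ENSDARG00000094183) rose by 6.71 ± 1.11 (adjusted p = 8.94e-05) from a mean of 14.7 to 1330 CPM, and 21 of 25 infected libraries lay above every uninfected library. The C-reactive protein gene crp6 rose by 6.73 ± 0.91 (adjusted p = 7.04e-06), with 19 of 25 infected libraries above all uninfected ones. The other genes with the largest rises were jac1, jac2 and jac3, the neuropeptide gene nmbb, the phosphate transporter slc34a2a and the chitinase gene chia.3, at 6.27 to 7.28. The chia.3 rise (7.23 ± 1.98, adjusted p = 0.00584) came from few libraries: 5 of 25 infected libraries lay above every uninfected one, and 16 lay below the uninfected median. The same held for slc34a2a, with 5 above and 16 below. For both genes these 5 libraries include inulin infected 5 and 6, the closest pair, which are not shown to come from separate fish. The jac genes, the chia genes and the copies of cxcl8b.1 have several members each, and reads shared between members were not checked here.

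Metabolic genes changed with infection as well. Of 29 tested genes of cholesterol biosynthesis 20 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). Without the libraries richest in ovary and testis genes (34 left) 16 of the 29 rose and 0 fell. The gene of the rate-limiting enzyme, hmgcra (ENSDARG00000052734), rose by 3.66 ± 0.67 (adjusted p = 0.000226), sqlea by 3.62 ± 0.69 and hmgcs1 by 2.07 ± 0.44. Of 36 glycolysis and gluconeogenesis genes 14 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0624 with an estimated correlation). The rises included lactate dehydrogenase ldha (ENSDARG00000101251) at 2.17 ± 0.30 (adjusted p = 1.14e-05), higher than the uninfected median in all 25 infected libraries, and hexokinase hk1 at 2.74 ± 0.41 (adjusted p = 2.81e-05). Oxidative phosphorylation genes rose by smaller amounts, 44 up and 3 down among 108 (50 and 4 adjusted over the list alone; adjusted p = 0.39 with an estimated correlation), for example uqcrc1 at 0.60 ± 0.10 (adjusted p = 9.37e-05). Among 31 antioxidant genes 11 rose and 3 fell (13 and 3 adjusted over the list alone; adjusted p = 0.215 with an estimated correlation), with txn at 2.51 ± 0.48 and gpx1b at 1.59 ± 0.31. Among 43 lipid absorption genes 10 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.786 with an estimated correlation), with slc27a4, a fatty acid transporter, at 1.49 ± 0.35.

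Pancreatic genes fell with infection. Of 32 exocrine pancreas genes 27 fell and 0 rose (28 and 0 adjusted over the list alone), with a median log2 fold change of -2.31 (adjusted p = 0.411 with an estimated correlation). The trypsinogen gene prss1 (ENSDARG00000042993) stood at a mean of 4530 CPM in infected and 23500 CPM in uninfected fish, a log2 fold change of -2.51 ± 0.59 (adjusted p = 0.00183). It was below the uninfected median in 24 of 25 infected libraries and was chosen after its values were seen. The transcription factor of acinar cells ptf1a fell by 2.25 ± 0.48 on the log2 scale (adjusted p = 0.000795). Of 14 endocrine pancreas genes 5 fell and 0 rose (6 and 0 adjusted over the list alone; fry adjusted p = 0.0562), with the somatostatin gene sst2 at -1.92 ± 0.70 (adjusted p = 0.0371). Red blood cell genes gave 9 falls and 1 rise among 15, also adjusted over the list alone (adjusted p = 0.677 with an estimated correlation), with the globin gene hbaa1 at -1.6 ± 0.44 (adjusted p = 0.00593).

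Gonad genes held the largest falls, and the 4 gonad-rich libraries were all uninfected. All 33 ovary genes fell, also adjusted over the list alone (adjusted p = 0.829 with an estimated correlation), as did 16 of 20 testis genes (17 fell and 1 rose adjusted over the list alone). The genes with the largest falls were efhb, gsdf (ENSDARG00000075301), znf541, hsf5, smc1b, kcnq1.2, piwil1 and hormad1, at -7.82 to -8.83, and in 5 of them the median uninfected library had no reads. Without the gonad-rich libraries 0 ovary genes fell and 13 of 32 rose, and 4 of 19 testis genes fell and 2 rose. Proliferation genes turned around with these libraries. Of 37 tested members 2 rose and 10 fell over all libraries (3 and 12 adjusted over the list alone), with a median of -0.35 beside an upward direction in fry's test (adjusted p = 0.858). Without the gonad-rich libraries 27 rose and 0 fell (32 and 0 adjusted over the list alone; adjusted p = 0.489 with an estimated correlation). With every library above 0.05% of reads on ovary and testis genes left out, 9 in all and 3 of them infected, 21 proliferation genes rose and 0 fell, and 1 of 25 ovary genes rose. For example, leaving out the 4 gonad-rich libraries, the thymidylate synthase gene tyms moved from -0.07 ± 0.39 (adjusted p = 0.926) to 1.47 ± 0.26 (adjusted p = 0.000271), and rrm1 from -0.50 ± 0.41 to 1.25 ± 0.24. Both were chosen after their values were seen.

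**Figure D3:**
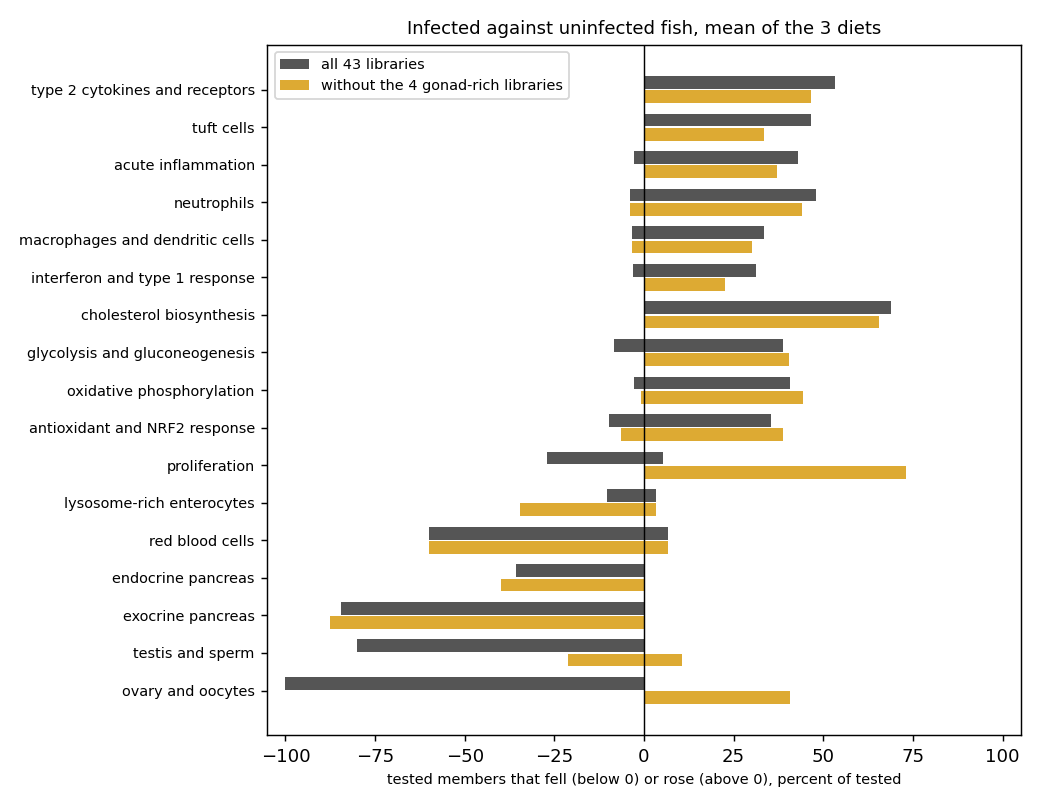
Percent of the tested members of 17 gene lists that rose (right of 0) or fell (left of 0) in infected against uninfected fish, mean of the 3 diets, over all 43 libraries (grey) and without the 4 gonad-rich libraries (yellow). Ovary genes go from 33 falls of 33 to 13 rises of 32, proliferation genes from 2 rises and 10 falls to 27 rises and 0 falls of 37, and exocrine pancreas genes from 27 to 28 falls of 32.

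In all, 1792 genes rose and 4534 fell with infection averaged over the diets by edgeR's quasi-likelihood test, and 28.3% of the changes were rises. Without the gonad-rich libraries 2816 rose and 1712 fell (62.2% rises), with 1326 of the rises and 1194 of the falls shared with the full set and 147 genes called in opposite directions. The median log2 fold change of all tested genes was -0.14 with all libraries and 0.02 without the gonad-rich ones.

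On each diet taken alone, il13 was among the genes that infection raised. It rose by 3.90 ± 1.09 on the control diet (adjusted p = 0.0447, n = 9 against 6), by 6.13 ± 1.24 on inulin (adjusted p = 0.0149, n = 8 against 6) and by 5.96 ± 1.23 on the egg diet (adjusted p = 0.0361, n = 8 against 6). The tuft cell factor pou2f3 rose by 2.86 ± 0.77 on the control diet (adjusted p = 0.0365) and by 3.24 ± 0.80 on the egg diet (adjusted p = 0.0422). On inulin it stood at 2.63 ± 0.77 (adjusted p = 0.0605). On the control diet 76 genes rose and 459 fell, and testis genes made up part of the falls, with 11 of 20 down (18 adjusted over the list alone). The balance turned to 37 rises and 17 falls with 2 surrogate variables and to 41 and 24 with tissue marker covariates. The rises there included the sodium-glucose transporter slc5a2 at 5.3 ± 1.5, the chemokine receptor ccr12b.1 at 4.58 ± 1.11, crp7 (ENSDARG00000071456) at 4.15 ± 1.18 and the glycolytic gene aldoaa at 1.17 ± 0.28, and hormad1, gsdf and tekt1 were among the largest falls. With only these groups fitted, or without the gonad-rich libraries, edgeR called 0 genes (3153 and 1710 at an unadjusted p under 0.05), while DESeq2 called 845 over all libraries.

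On inulin 234 genes rose and 163 fell. Cholesterol biosynthesis genes rose in 8 of 29 cases and fell in 0 (19 and 0 adjusted over the list alone; adjusted p = 0.228 with an estimated correlation), with hmgcra at 6.24 ± 1.33 (adjusted p = 0.0199) and ldlrb, a receptor for cholesterol-carrying lipoprotein, at 2.67 ± 0.54 (adjusted p = 0.0149). Acute inflammation genes rose in 4 of 35 cases and fell in 0 (11 and 1 adjusted over the list alone), with ptgs2b at 2.71 ± 0.68. Glycolysis genes rose in 6 of 36 cases and fell in 0 (14 and 2 adjusted over the list alone), with ldha at 2.82 ± 0.55 (adjusted p = 0.0121). The exocrine gene spink4 fell by 4.04 ± 0.94 on the log2 scale (adjusted p = 0.023), as the only exocrine gene past the threshold, with 27 of 32 down adjusted over the list alone. The muscle myosin gene myhb also counted among the largest rises, but only 1 of 8 infected libraries lay above all uninfected ones. The number of changed genes was 171 with only these groups fitted and 1936 without the gonad-rich libraries, of which inulin uninfected 3 belongs to this comparison.

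On the egg diet 64 genes rose and 135 fell. The largest rises included sts at 7.81 ± 2.02 (adjusted p = 0.0487), crp6, the cystatin gene cst14b.2 at 6.18 ± 1.61, cxcl8b.1 (ENSDARG00000102299) at 4.4 ± 1.0 (adjusted p = 0.0393), the transcription factor batf2 at 3.59 ± 0.89 and hk1 at 3.42 ± 0.74. The largest falls were in samd7 (-9.1), cbln1 (-7.70), calml4b (-6.52) and inavaa (-6.13). Also among the 8 largest were slc16a5a at -5.21 ± 1.18 and rbpms2b at -4.50 ± 1.06. Without the gonad-rich libraries rbpms2b moved to -0.31 ± 0.43 (adjusted p = 0.773) and slc16a5a to -0.26 ± 0.81 (adjusted p = 0.91). Cholesterol biosynthesis genes did not pass the test over all genes here (11 of 29 rose adjusted over the list alone), with hmgcra at 3.74 ± 1.17 (adjusted p = 0.0713). The count of changed genes was 1 with only these groups fitted, 19 with the range of library numbers as a covariate, and 288 without the gonad-rich libraries. Of these 288 genes 58.7% rose. The gonad-rich library egg uninfected 5 belongs to this comparison. Only 44 of the 64 rises and 31 of the 135 falls were called again without the gonad-rich libraries, so most of the falls did not hold.

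Some changed genes were shared between the diets. In these comparisons, which share no libraries, 20 genes rose and 2 fell on all 3 diets, among them il13, crp6, myh11b and btk (up) and arl4d and trim71 (down). Rises on the control diet and on inulin shared 39 genes, against 0.78 for independent lists, and falls shared 13 against 3.3. Control and egg shared 22 rises against 0.21 and 3 falls against 2.7. Inulin and egg shared 40 rises against 0.66 and 32 falls against 0.97. The log2 fold changes of the 22690 genes correlated with Pearson's r = 0.62 between control and inulin, 0.58 between control and egg and 0.74 between inulin and egg (Spearman's rho 0.51, 0.52 and 0.67). These are correlations across genes, which are not independent replicates. On the control diet 0 genes passed by edgeR without the gonad-rich libraries (1710 at an unadjusted p under 0.05), so that 0 were shared with it, while inulin and egg shared 131 rises against 9.3 and 67 falls against 3.5. The values of r over 22824 genes were then 0.24 between control and inulin, 0.19 between control and egg and 0.56 between inulin and egg.

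Fish on the egg diet had higher levels of sterol synthesis and fatty acid oxidation genes than fish on the control diet, in the average of infected and uninfected fish. In uninfected fish alone 0 genes passed by edgeR (2849 at an unadjusted p under 0.05, 261 by DESeq2). Averaged over infected and uninfected fish, 13 of 29 cholesterol biosynthesis genes rose and 0 fell (23 and 0 adjusted over the list alone; adjusted p = 0.251 with an estimated correlation). The lanosterol demethylase gene cyp51 (ENSDARG00000042641) rose by 2.92 ± 0.63 (adjusted p = 0.0216, n = 14 against 15), the farnesyl diphosphate synthase gene fdps (ENSDARG00000040890) by 2.31 ± 0.51 (adjusted p = 0.0243), and acat2 by 1.79 ± 0.37 (adjusted p = 0.0179), higher than the control median in 13 of 14 egg-fed fish. Of 43 genes of fatty acid oxidation and PPAR signalling 9 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 0.397 with an estimated correlation), with the beta-oxidation genes hadhab at 0.95 ± 0.18 (adjusted p = 0.0103), ech1 at 0.97 ± 0.22 and cpt2 at 0.83 ± 0.17. Of 108 oxidative phosphorylation genes 20 rose and 1 fell (71 and 1 adjusted over the list alone; adjusted p = 0.251 with an estimated correlation), with atp5mc1 at 1.02 ± 0.20 (adjusted p = 0.0117), above the control median in all 14 egg-fed fish. Among 26 fatty acid synthesis genes 2 rose and 0 fell (4 and 0 adjusted over the list alone), aclya at 0.98 ± 0.20 and elovl6 at 2.14 ± 0.58.

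**Figure D4:**
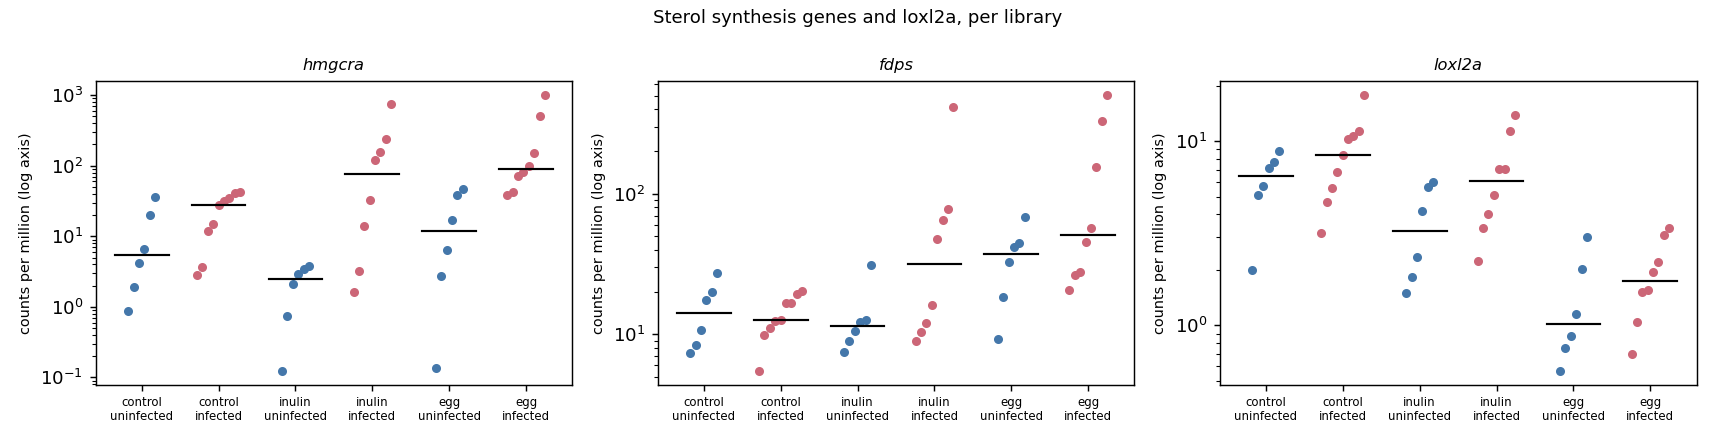
CPM (log axes) of hmgcra, fdps and loxl2a for each library, by group; points are libraries and black lines are medians. For loxl2a all 14 egg-fed fish lie below the median of the control diet, while fdps averages 146 CPM in infected egg-fed fish and 13.8 CPM in infected fish on the control diet.

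The clearest fall on the egg diet was in loxl2a (ENSDARG00000044010), which encodes a lysyl oxidase that crosslinks collagen. It stood at a mean of 1.7 CPM against 7.67 on the control diet, a log2 fold change of -2.14 ± 0.32 (adjusted p = 0.000805), and all 14 egg-fed fish lay below the control median. Of 58 extracellular matrix genes 3 fell and 0 rose (10 and 0 adjusted over the list alone; adjusted p = 0.352 with an estimated correlation), the others being postnb at -1.44 ± 0.34 and mmp2 at -0.94 ± 0.23. Of 20 glucocorticoid response genes 1 fell and 0 rose (10 and 0 adjusted over the list alone; adjusted p = 0.352 with an estimated correlation). It was fkbp5, a steroid receptor chaperone induced by cortisol, at -2.12 ± 0.54 (adjusted p = 0.0368). Of 36 circadian clock genes 1 fell and 0 rose (4 and 0 adjusted over the list alone; adjusted p = 0.251 with an estimated correlation), namely tefb at -0.98 ± 0.25. The genes ccdc65, rsph4a and ccdc78 were among the largest falls, as was the tubulin gene tuba7l at -3.38 ± 0.89. Of these, tuba7l stood at 0.65 ± 0.53 (adjusted p = 0.537) and rsph4a at -0.63 ± 0.92 (adjusted p = 0.763) without the gonad-rich libraries, 2 of which are on the control diet. The yolk protein gene vtg5, at -10.55 ± 2.83, rested on few fish: vitellogenin genes took 5.08% of the reads in control infected 2 and 2.07% in control infected 5.

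In all, 173 genes rose and 179 fell between the egg and control diets averaged over infection, and 261 rose and 271 fell without the gonad-rich libraries, with 107 and 114 shared. The count was 103 with no filter on low counts and 2381 with 2 surrogate variables. In infected fish 13 genes rose and 3 fell (n = 8 against 9), with 4 of 29 cholesterol genes up and 0 down (23 and 0 adjusted over the list alone; adjusted p = 0.0975 with an estimated correlation). They were cyp51 at 4.17 ± 0.83 (adjusted p = 0.0341), lss at 3.61 ± 0.72, fdps at 3.4 ± 0.67 and pmvk at 1.96 ± 0.41. The largest rises also included the glucokinase gene gck at 3.87 ± 0.82 (adjusted p = 0.0497), which lay above all control fish in 5 of 8 fish and below their median in the other 3, the retinol dehydrogenase rdh12 at 3.46 ± 0.71 and the chaperone calr at 1.6 ± 0.32. The gene syt5a had no reads in the 9 control fish and the loxl2a fall was -2.18 ± 0.41 (adjusted p = 0.0305). This count was 570 without the gonad-rich libraries, which are not among these 2 groups but share the estimate of spread, and 387 with only these groups fitted. It was 9 with RLE factors, 8 with the closest pair summed, 5 with the range of library numbers as a covariate and 0 by edgeR with no filter on low counts (3633 at an unadjusted p under 0.05). In uninfected fish edgeR called 0 genes (n = 6 against 6), with 2849 at an unadjusted p under 0.05 and 261 by DESeq2, and 0 without the gonad-rich libraries (2218 at an unadjusted p under 0.05). There loxl2a stood at -2.11 ± 0.48 (adjusted p = 0.118) and cpt2 at 1.17 ± 0.26 (adjusted p = 0.118), and 14 of 43 fatty acid oxidation genes rose adjusted over that list alone (1 fell).

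Inulin gave no change past the threshold against the control diet. By edgeR 0 genes passed in uninfected fish, in infected fish and in the average of both, with 1058, 1742 and 1617 at an unadjusted p under 0.05, while DESeq2 called 15, 97 and 47. These counts were also 0 without the gonad-rich libraries (1380, 3161 and 2362 at an unadjusted p under 0.05). Liver genes were higher on average, 36 of 39 up and 0 down adjusted over the list alone and 0 over all genes (adjusted p = 0.71 with an estimated correlation), as were skeletal muscle genes, 15 of 21 up and 0 down adjusted over the list alone (adjusted p = 0.71 with an estimated correlation). Liver genes took 11.3% of the reads in inulin uninfected 2, 8.26% in inulin infected 5 and 8.03% in inulin infected 6, the closest pair. The median liver share was 0.558% on inulin and 0.224% on the control diet in uninfected fish, but 0.353% and 0.653% in infected fish. Neither il13 (-0.13 ± 0.65, adjusted p = 0.985) nor loxl2a (-0.57 ± 0.30, adjusted p = 0.749) passed the test, and both were chosen after their values were seen. The inulin and egg effects against the shared control fish correlated across genes with r = 0.53 (covariance 0.309). With all 43 libraries, the controls included, simulated from the overall mean of each gene and no effect, r averaged 0.48 (covariance 0.269) over 5 simulations. With the real controls split between the comparisons r was 0.09 and 0.14 (covariance 0.144 and 0.204).

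Between the egg and inulin diets edgeR called 0 genes (1876 at an unadjusted p under 0.05; 114 by DESeq2), and 22 without the gonad-rich libraries. Of 29 cholesterol genes 4 rose on egg adjusted over the list alone (adjusted p = 0.552 with an estimated correlation), with lss at 1.65 ± 0.54 (adjusted p = 0.323, n = 14 against 14). Of 58 extracellular matrix genes 6 fell adjusted over the list alone (adjusted p = 0.552 with an estimated correlation). The loxl2a gene stood at -1.58 ± 0.31 (adjusted p = 0.0916) and passed without the gonad-rich libraries (adjusted p = 0.0402).

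The test of a response to infection that depends on diet called 1 gene, which did not pass with no filter on low counts (-1.7, adjusted p = 0.144). The gene si:ch211-74f19.2 (ENSDARG00000076239) went from a mean of 16.2 to 33.7 CPM with infection on the control diet and from 27.5 to 16.5 CPM on the egg diet, an interaction of -1.79 ± 0.29 (adjusted p = 0.00899). It was the single gene past the threshold (1262 at an unadjusted p under 0.05; 52 by DESeq2), the count without the gonad-rich libraries was also 1, and on inulin its mean was 18.5 CPM in uninfected and 17.7 CPM in infected fish. The interaction of infection with inulin gave 0 genes by edgeR (1218 at an unadjusted p under 0.05; 38 by DESeq2), and 0 without the gonad-rich libraries (1765 at an unadjusted p under 0.05). The hmgcra response was larger on inulin than on the control diet by 5.23 ± 1.49, a difference that did not pass over all genes (adjusted p = 0.732). Of 29 cholesterol genes 15 had a larger response on inulin adjusted over the list alone (adjusted p = 0.312 with an estimated correlation). The il13 response differed by 2.22 ± 1.33 on inulin (adjusted p = 0.948) and by 2.06 ± 1.33 on egg (adjusted p = 0.989), and the pou2f3 response by -0.23 ± 0.98 and 0.38 ± 0.98. These 3 genes were chosen after their values were seen.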

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

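The tests of explanations in this part, and the fits without the 4 gonad-rich libraries, were chosen only after the result was seen.

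More genes fell than rose with infection, and RNA from gonads in 4 uninfected libraries is a candidate explanation. Without these libraries 62.2% of the called genes rose, against 28.3% with all 43, in the mean of the diets, and 65.7% rose without all 9 libraries, 3 of them infected, above 0.05% of reads on ovary and testis genes. Lower gonad transcripts across infected fish cannot be told apart from it: 0 of 32 tested ovary genes fell without these libraries, but 2 of 33 had a median of at least 1 CPM there, so a fall could hardly show, and 13 of the 32 rose, beside higher ovary shares left in 3 infected libraries. Only 2 ovary genes and 1 testis gene also stand in another fixed list, while 4 of 19 testis genes still fell and 2 rose without these libraries. Sex and trimming of single fish stay open as reasons why the 4 libraries are uninfected, and neither was tested.

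Exocrine pancreas genes were lower with infection, with 27 of 32 falling. RNA from gonads is argued against, since exocrine genes took at most 8.33% of the reads in the 4 gonad-rich libraries, under the median of 14.5% in the uninfected ones, so these libraries lower the uninfected side. Less pancreatic tissue in the libraries of infected fish may account for the fall: within groups the exocrine and endocrine lists moved together across 43 libraries (Pearson's r = 0.68, permutation p = 1e-05, the smallest they can give, adjusted p = 0.00012 over 36 relations; Spearman's rho = 0.66, adjusted p = 0.00018; r = 0.64 without the 2 farthest libraries). Lower transcription in an unchanged amount of pancreas cannot be told apart from it, since the endocrine list gave an adjusted p by fry of 0.0562 over all libraries and 0.0146 without the gonad-rich ones, and 7 of its 14 genes also stand in other lists. The exocrine list moved as closely with smooth muscle genes (r = 0.77), which lie outside the pancreas, so the relation is not specific to it, and whether less pancreas was dissected or present in infected fish was not tested.

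Cholesterol biosynthesis genes were higher on the egg diet, with 13 of 29 rising in the mean of infected and uninfected fish. With the exocrine pancreas, liver and ovary lists as covariates 13 were called higher, so liver RNA as marked by its list does not account for all of the rise. These covariates also took the calls over all genes from 352 to 1524. The unchanged 13 therefore does not show that the effects kept their size, and a part played by liver RNA stays open. Whether the egg diet acts in uninfected and infected fish alike is left open: the list's adjusted p by fry was 0.71 in uninfected fish (median log2 fold change 0.86), 0.0349 in infected fish (1.99) and 0.988 for the interaction. In uninfected fish 0 of these members passed edgeR's test over all genes (2849 genes at an unadjusted p under 0.05, 261 by DESeq2), and differences in feeding between the groups stay open as untested.

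Single libraries lay far from the rest of their group in 17 of 72 combinations of a measure and a group. The cut-offs pick about 1 in 20 groups of normally distributed values. Most of these measures are skewed CPM values or shares of reads, and several move together. The count of 17 therefore cannot be set against chance. Exocrine genes took 24.9% of the reads in control infected 8 (next 9.09%) and 9.3% in inulin infected 8 (next 3.42%). The same libraries stood out for prss1, with 30600 CPM in control infected 8 (next 8110) and 8980 CPM in inulin infected 8 (next 3390), and inulin infected 8 had 226 CPM of myh11b (next 83.1). Liver genes took 11.3% of the reads in inulin uninfected 2 (next 0.873%) and 12.9% in egg infected 3 (next 1.7%). For il13 the libraries apart were control uninfected 2 with 8.88 CPM (next 2.43), control infected 9 with 182 (next 58.6) and egg infected 6 with 483 (next 122). For sts they were control uninfected 3 with 113 CPM (next 19.1), inulin uninfected 1 with 72.3 (next 3.86) and egg uninfected 1 with 33.9 (next 1.13). Inulin infected 2 had 744 CPM of hmgcra (next 242) and 412 CPM of fdps (next 78.3), and inulin uninfected 3 had 31.1 CPM of fdps (next 12.6). Egg uninfected 3 held 40.24 M reads (next 34.27 M).

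The response of si:ch211-74f19.2 to infection differed between the egg and control diets by the test of the interaction itself (-1.79, adjusted p = 0.00899 by edgeR), a count of 1 gene for which chance cannot be excluded (8 of 100 splits of the libraries gave as many, highest other 2722).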

How the results depend on the processing

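Of the tests in this part, the fits without the gonad-rich libraries, without the libraries over a stricter gonad limit and with the closest pair summed were chosen only after the result was seen. For single genes, 2302 of 2869 values under the alternatives counted as unchanged, from 178 of 310 with the replicate block to 306 of 310 with RLE factors. These kept their direction and their side of the threshold, or turned their direction without having passed over all libraries. The latter include values that newly passed, such as tyms for infection without the gonad-rich libraries. A further 481 kept their direction and no longer passed, and 60 kept it and newly passed. Among values that had passed over all libraries, 26 turned their direction. Depth was similar in all libraries, so it limits little beyond genes near the filter. Counts of called genes that moved by more than 1.5 times follow, each beside the count by edgeR over all libraries, and the cause was not tested except where the construction shows it.

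The counts over all libraries were 535, 397 and 199 for infection on the control, inulin and egg diets and 6326 in their mean, 0, 16 and 352 for egg against control in uninfected fish, infected fish and the mean, 0 in each of the 3 for inulin against control, 0 for egg against inulin, and 0 and 1 for the interactions with inulin and egg. With tissue marker covariates infection gave 65 on the control diet, 1388 on inulin and 3874 in the mean. Inulin against control gave 3 in uninfected fish, 10 in infected fish and 3 in the mean, egg against control 87, 30 and 1524, egg against inulin 41, and the interactions 12 (inulin) and 3 (egg). With 2 surrogate variables infection gave 54, 2051 and 577 on the control, inulin and egg diets. Inulin against control gave 1 in uninfected fish, egg against control 493, 410 and 2381, egg against inulin 33, and the interactions 2 and 15. With this setting the fold changes of infection on the control diet correlated at 0.40 with inulin (0.62 over all libraries) and 0.21 with egg (0.58). DESeq2 called 845, 1404 and 1892 for infection on the 3 diets, 15, 97 and 47 for inulin against control, 261, 230 and 1227 for egg against control, 114 for egg against inulin, and 38 and 52 for the interactions. RLE factors gave 792 for infection on the egg diet (166 rose and 626 fell, 21% rises, against 64 and 135, 32.2%) and 9 for egg against control in infected fish. Their median over all genes for infection in the mean of the diets was -0.15, against -0.14 with TMM.

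With no filter on low counts, which adds tests, infection gave 850 on the control diet and 0 on the egg diet, egg against control 0 in infected fish and 103 in the mean, and the interaction with egg 0 (6782, 3633 and 2507 at an unadjusted p under 0.05 beside the counts of 0 by edgeR). With the closest pair summed egg against control in infected fish gave 8. With the range of library numbers as a covariate infection on the egg diet gave 19 and egg against control in infected fish 5. With the groups compared only, infection gave 0 on the control diet (3153 at an unadjusted p under 0.05), 171 on inulin and 1 on the egg diet, and egg against control 387 in infected fish. Without the gonad-rich libraries infection gave 0 on the control diet (1710 at an unadjusted p under 0.05) and 1936 on inulin, egg against control 570 in infected fish and 532 in the mean, and egg against inulin 22, while the correlations with the control diet were 0.26 (inulin) and 0.20 (egg) over genes also tested with all libraries. Without the 9 libraries above 0.05% of reads on ovary and testis genes infection gave 2793 in the mean of the diets (1836 rose and 957 fell, in 12 uninfected and 22 infected libraries), of which 1726 rises and 907 falls were shared with the fit without the gonad-rich libraries. Of the 249 list changes called by camera with the preset correlation, 0 passed with an estimated correlation, and fry called 28.

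With the replicate block infection gave 0 on the control diet, 116 on inulin, 2 on the egg diet and 3016 in the mean, egg against control 0 in infected fish and 42 in the mean, and the interaction with egg 0 (2695, 2119 and 902 at an unadjusted p under 0.05 beside the counts of 0). The numbers are not shown to pair fish: 96 pairs of libraries with one number had a mean correlation of deviations of -0.005 (lowest -0.516, 27 over 0.1), against 0.005 for different numbers. Of 43 libraries 10 were closest to one with their own number.

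The 26 values that had passed over all libraries and turned came from 3 settings. Without the gonad-rich libraries dnah5l on the control diet moved to 3.95, mkrn4 on the egg diet to 0.01, tuba7l for egg against control to 0.65, and, for infection in the mean of the diets, insb to 0.53, mos to 0.42, nitr9 to 0.57 and wee2 to 0.10. With 2 surrogate variables, tissue marker covariates and without the gonad-rich libraries, in this order, aurka moved to 0.58, 0.59 and 1.33, birc5b to 4.79, 1.31 and 5.35, ccnb1 to 0.72, 0.85 and 1.25, ccnb2 to 0.65, 0.77 and 1.15, and chia.4 to 0.44, 0.87 and 1.31. The gene eomesa moved to 0.24 with 2 surrogate variables and 0.75 without the gonad-rich libraries. With tissue marker covariates cpa5 moved to 0.01 and ghrl to 0.12. All were below 0 over all libraries, and for the settings other than leaving out the gonad-rich libraries the cause was not tested.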

Other observations

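In this part the relations between lists, the libraries rich in proximal gut genes and the other splits of the libraries were tests chosen only after the result was seen.

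Further gene lists held changed genes with infection in the mean of the diets (n = 25 against 18). Over all 22690 tested genes 1792 rose and 4534 fell. A list can therefore hold several changed genes without standing out, here and among the epithelial cell types below. Of 29 heat shock genes 9 rose and 5 fell (11 and 6 adjusted over the list alone; adjusted p = 0.677 with an estimated correlation), and 14 rose and 0 fell without the gonad-rich libraries. The chaperone gene hsp70.1 rose by 2.47 ± 0.62 and hspa8 by 0.57 ± 0.12 (adjusted p = 0.000607). Of 58 extracellular matrix and wound repair genes 14 rose and 2 fell (18 and 2 adjusted over the list alone; adjusted p = 0.677 with an estimated correlation). Among them tnca, which encodes tenascin C, a matrix protein of healing tissue, rose by 1.67 ± 0.32 (adjusted p = 0.000309), while the protease inhibitor gene timp2a stood at -0.86 ± 0.20 (adjusted p = 0.00181). In the eosinophil and mast cell list 4 of 12 genes rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation). The rises included the transcription factor gata1a at 2.51 ± 0.53 (adjusted p = 0.000697), and the falls the mast cell carboxypeptidase cpa5 at -2.29 ± 0.61 (0.01 with tissue marker covariates, among them the exocrine pancreas list). Of 16 genes of NK-like and cytotoxic lymphocytes 2 rose and 2 fell, also adjusted over the list alone. The largest rise there was the NK-lysin gene nkl.2 at 5.91 ± 1.15 (adjusted p = 0.000385), with 10 of 25 infected libraries above all uninfected ones.

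Among epithelial cell types 4 of 25 goblet cell genes rose and 0 fell, also adjusted over the list alone, with agr2, a disulfide isomerase needed for mucin folding, at 1.69 ± 0.35 (adjusted p = 0.000666). Of 37 enteroendocrine genes 1 rose and 6 fell (0 and 0 adjusted over the list alone), with the ghrelin gene ghrl at -1.70 ± 0.56 (adjusted p = 0.0211; 0.12 with tissue marker covariates) and pyyb at 2.81 ± 0.97 (adjusted p = 0.0267). The counts without the gonad-rich libraries were 2 rises and 11 falls (4 and 13 adjusted over the list alone; adjusted p = 0.737 with an estimated correlation). Of 29 genes of lysosome-rich enterocytes, the protein-absorbing cells of the distal gut, 1 rose and 3 fell (1 and 2 adjusted over the list alone; adjusted p = 0.786 with an estimated correlation), with lamp2 at -0.87 ± 0.24 (adjusted p = 0.00705). Without the gonad-rich libraries 1 rose and 10 fell (1 and 12 adjusted over the list alone; adjusted p = 0.489 with an estimated correlation). On the egg diet against the control diet 1 of 25 T cell genes fell and 0 rose, also adjusted over the list alone (adjusted p = 0.423 with an estimated correlation), tagapb (ENSDARG00000043475) at -1.09 ± 0.29 (adjusted p = 0.0443).

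Within groups, fish with higher type 2 cytokine genes also had higher tuft cell genes. Across 43 libraries the list means, as deviations from the group means, correlated with Pearson's r = 0.75 and Spearman's rho = 0.80 (permutation p = 1e-05 for both, the smallest they can give; adjusted p = 0.00012 and 0.00018 over 36 relations). The value was 0.75 without the 2 farthest libraries, 0.72 without the gonad-rich ones, 0.72 among the 25 infected libraries, and 0.77 and 0.75 among low and high library numbers (n = 20 and 23). Tuft cells may be more numerous or more active in fish with a stronger type 2 cytokine response, a hypothesis found and tested on the same data, and worm burden as a common driver was not tested. Both lists were lower where absorptive enterocyte transport genes were higher among the 25 infected libraries (r = -0.67 for type 2 and -0.66 for tuft; -0.53 and -0.47 without the gonad-rich libraries), while over all 43 the values were -0.20 (adjusted p = 0.34) and -0.10 (adjusted p = 0.63). The mix of tissue or gut segment therefore stays open as another explanation.

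Several genes of the proximal gut were high in the same 5 infected libraries. The closest pair, inulin infected 5 and 6, is among them, so the 5 libraries may come from fewer than 5 fish. In control infected 1, inulin infected 6, inulin infected 5, egg infected 1 and inulin infected 3, chia.3 stood at 46800, 39100, 38100, 9030 and 1170 CPM (next library 738). In the same order slc34a2a stood at 2320, 818, 842, 655 and 298 CPM (next 75.2), slc6a19a.1 at 964, 1340, 1420, 233 and 214 (next 68.9) and lct at 18.5, 119, 114, 737 and 125 (next 15.3). These libraries could hold more proximal and less distal gut. The test, opposite movement of the absorptive transport and lysosome-rich enterocyte lists within groups, left this open, with Pearson's r = 0.06 (permutation p = 0.72, adjusted p = 0.76) and Spearman's rho = -0.04 (permutation p = 0.83, adjusted p = 0.88). It was -0.37 without the 2 farthest libraries, -0.47 among the 25 infected libraries, and -0.46 and 0.38 among low and high library numbers (n = 20 and 23).

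Each count of called genes was set against splits of the same libraries into groups of the same sizes, 100 per comparison with the real one included. For infection averaged over the diets 1 of 100 splits, the real one, reached 6326 genes (highest other 2474). The same held for inulin (397, 1 of 100, highest other 102). Chance is unlikely for these counts. It is not excluded, since 1 of 100 is the smallest share the splits can give and shares were not corrected over the comparisons. Single fish were shuffled, so differences between tanks, which are not given, were not covered. For the control diet 2 of 100 splits reached 535, a share under 0.05, but the other one called 789, more than the real groups, and the count was 0 without the gonad-rich libraries. For infection on the egg diet chance cannot be excluded over all libraries: 7 of 100 splits reached 199, and 1 called 1061. For egg against control in infected fish chance is unlikely, with the same limits (16, 1 of 100, highest other 1). Chance cannot be excluded for the mean of infected and uninfected fish (352, 8 of 100, highest other 2347). Nor can it for the interaction with egg (1, 8 of 100, highest other 2722). In the comparisons with 0 genes by edgeR all 100 of 100 splits gave as many by construction, which says nothing about chance, and the highest others were 2478, 52 and 1057 for inulin against control in uninfected fish, in infected fish and in the mean. They were 4157 for egg against control in uninfected fish, 1849 for egg against inulin and 749 for the interaction with inulin. At an unadjusted p under 0.05 these 6 comparisons gave 1058, 1742, 1617, 2849, 1876 and 1218 genes, and by DESeq2 15, 97, 47, 261, 114 and 38. Splits that call several times the real count point to a structure of the samples.

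The same splits without the gonad-rich libraries called fewer genes. There 1 of 100 splits, the real one, reached 1936 genes for infection on inulin (highest other 214), 288 on the egg diet (highest other 1) and 4528 in the mean of the diets (highest other 263). It also was the single split to reach 570 for egg against control in infected fish (highest other 1) and 532 in the mean (highest other 0). Chance is unlikely for these 5 counts, with the same limits as above. It cannot be called unlikely for the interaction with egg (1, 5 of 100, highest other 70). The splits say nothing about chance for infection on the control diet (highest other 16) and egg against control in uninfected fish (highest other 1), where the real count was 0. The 2 counts of 0 by edgeR stood beside 1710 and 2218 genes at an unadjusted p under 0.05, and DESeq2 was not run without these libraries.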
